A study of Pseudomonas putida KT2440 with 14 samples.

How the data were processed

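RNA was sequenced from 14 cultures of 7 evolved isolates of engineered Pseudomonas putida KT2440, 8 libraries from 4 isolates on xylose and 6 libraries from 3 isolates on galactose, with 2 biological duplicates per isolate. Per the labels' protocols, cells grew at 30 °C in a modified M9 minimal medium with 4 g/L of the sugar and were sampled in exponential phase at an OD600 of 0.4 to 0.6. Ribosomal RNA was removed with oligonucleotides and RNase H after DNase I treatment, and paired-end libraries were made with a KAPA HyperPrep kit, per the labels' protocols.

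The values used are those the authors deposited in a table per sugar, in TPM (length-scaled transcript abundances), with a column per library. Each column summed to 1000000, so TPM are shares within a library and a change in a few abundant genes moves all others. Per the submitters' processing notes, Bowtie2 and DESeq2 were used. Their versions, the read counter, the annotation and the genome build are not given in the sources used here. Both tables list genes by locus tag, and 5483 tags were in both. A reference gene table held 5723 genes and matched 0 of the tags, so no symbols or coordinates are given. What a tag encodes is stated only for members of lists fixed by tag, as background knowledge that was not checked against an annotation, and other tags are limited to 2 that rose and 2 that fell in each comparison.

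Xylose columns were assigned to isolates A1 to A4 by the sample descriptions, which hold the column headings. The descriptions of the galactose samples hold no headings, and nothing ties the numbers 1 to 3 in the column headings to the isolate names in the labels, so the heading numbers are used. The replicates are separate cultures per the labels.

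TPM keep no sequencing depth, but ratios between libraries of a sugar gave whole reads for 5497 of 5501 genes (99.927%) on xylose and 5493 of 5498 (99.909%) on galactose, at a tolerance of 0.02. On data simulated from the recovered genes alone, this recovery was exact for 98.981% of genes on xylose and 97.724% on galactose. The recovered genes held 93.8 to 96.5% of the TPM of a library, so that abundant genes were among those missed. Between 117 and 192 genes were listed at 0 per library. Duplicates differed by more than counting noise, with a chi-square per gene of 3.38 to 20.1, and were counted as 2 samples.

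The design, tests, lists and alternatives were fixed before the data were examined, except where stated. Genes with a mean TPM of at least 1 over the libraries of a sugar were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderation. All isolates of a sugar entered 1 fit without a replicate block, with 4 residual degrees of freedom on xylose and 3 on galactose. Each isolate was set against the equally weighted mean of the others on its sugar, and a moderated F test asked for any difference. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold change. Higher or lower than each single other isolate means that every pairwise contrast passed both limits. A gene lay beyond the other libraries when both of its libraries were above, or both below, all of them. Because the isolates of a sugar share libraries, their contrasts are not independent and overlaps between them are not given.

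Before the data were examined 32 gene lists were fixed, and 1 of ribosomal protein genes was added by tag range after the tags but before the values were seen, since lists fixed by symbol or product could not be resolved. Lists with at least 3 tested genes entered limma's camera test with a preset correlation of 0.01, adjusted over lists and contrasts of a sugar. Of 120 pairs of list and contrast on xylose 36 were called, and of 93 on galactose 33. With an estimated correlation 0 were called on either sugar, at an unadjusted p below 0.05 24 and 7 pairs, and with limma's fry 42 and 54. The count "adjusted over the list alone" repeats the gene test with adjustment among the members only.

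Genes were named by a rule: the largest 10 rises and 10 falls among called genes beyond all other libraries, the called members of the sugar route lists, and the levels of introduced genes and of PP_1015, PP_1010 and PP_1444. The result of 1 item that the rule names is not reported here. The limit on tags without a function means that the rule is not printed in full, and other list members were chosen as examples after their values were seen. Runs are at least 5 neighbouring tested genes by tag called in 1 direction, compared with 1000 shuffles of the gene order. Across sugars, isolate means were compared without a test, and a difference needed no overlap of the means and a 4-fold difference.

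In simulated data with 200 changed genes in each contrast, changes of 1.5 on the log2 scale were called in 96 to 100% of cases and changes of 3 in 100%, with 0 to 5 false calls. A list shifted by 1 was called and 0 others were. In each simulation only the isolate of the contrast was changed. The false calls therefore do not cover genes called in an isolate because another isolate in the mean differs. The simulated noise was normal and independent between genes, and changed genes were drawn above a minimum level. The list result therefore does not cover lists with correlated members, and in the data the Entner-Doudoroff list on xylose had an estimated correlation of 0.798. Alternatives were other pseudocounts (0.1 and 10), no filter and a mean TPM of 10, median centring and quantile normalization, no variance trend, a replicate block, leaving out each library in turn, no fold limit and other list and run settings. A fit with limma voom on recovered reads was added after the data were seen. It could not test genes without recovered reads, among them xylD. It held 14 of 15 sugar acid genes on xylose and 4 of 6 glucose uptake genes on galactose. A fit without a library leaves 1 sample for its isolate, which is then assumed to vary like the others. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.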

Results

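Pseudomonas putida KT2440 is a soil bacterium that grows on glucose but not, without engineering, on xylose or galactose. Transcriptomes were measured in 7 isolates of engineered KT2440 that had been evolved on these sugars. The 4 xylose isolates A1_F11_I1, A2_F10_I1, A3_F14_I1 and A4_F11_I1, called A1, A2, A3 and A4 here, carried xylD, an introduced xylonate dehydratase gene. The 3 galactose isolates carried introduced Escherichia coli genes of galactose breakdown, including galT, galK and galM, and are called galactose isolates 1, 2 and 3 after the column headings. Their labels are A5_F85_I1, A6_F90_I1 and A8_F92_I1, which nothing ties to the numbers. Each isolate was represented by 2 libraries from biological duplicate cultures, 14 libraries in all, with no unevolved reference strain analysed here. The question the design allows is therefore how separately evolved isolates on the same sugar differ from each other. Values were TPM, transcript abundances scaled to sum to 1000000 in each library, for 5501 genes on xylose and 5498 genes on galactose. Whole reads recovered from the TPM values came to 3415915 (A3 replicate 1) to 6363051 (A4 replicate 1) per library on xylose and 4039880 to 5736268 on galactose. Log2 levels of the 2 libraries of an isolate correlated across genes with r of 0.978 to 0.987 on xylose and 0.986 to 0.987 on galactose, and libraries of different isolates with r of 0.932 to 0.978 and 0.883 to 0.965 (genes are not independent replicates). Levels below are mean TPM ± SD of n = 2 libraries. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes at low levels, and set an isolate against the mean of the other isolates on its sugar.

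On xylose, all 4 isolates expressed xylD and 5 of the 15 genes of the sugar acid list at high levels. The level of xylD was 14638 ± 1893 TPM in A1, 16881 ± 2344 in A2, 18051 ± 772 in A3 and 13375 ± 1584 in A4, and no isolate passed the test for it (limma, adjusted p from 0.14 to 0.56). PP_2834 to PP_2837, in the list of pentose, uronate and aldarate oxidation, and PP_2585, a semialdehyde dehydrogenase gene of the same list, stood between 4638 ± 281 TPM (PP_2585 in A4) and 11869 ± 567 TPM (PP_2837 in A3). The 2-ketogluconate genes PP_3376 to PP_3379 ranged from 3950 ± 197 TPM (PP_3379 in A4) to 9693 ± 610 TPM (PP_3377 in A2). PP_1015, the binding protein of the glucose transporter, lay at 2387 ± 72.9 to 2667 ± 371 TPM. PP_1010, the Entner-Doudoroff dehydratase, lay at 57.2 ± 1.75 to 74.8 ± 16.3 TPM, and PP_1444, the periplasmic glucose dehydrogenase, at 145 ± 2.75 to 218 ± 7.71 TPM. Against the mean of the others, PP_2837 was at −0.86 ± 0.09 (SE) in A1 with adjusted p = 0.00037 and 0.90 ± 0.09 in A3 with adjusted p = 0.00024 (limma), each short of 2-fold. Its level was 4766 ± 44.6 TPM in A1 and 11869 ± 567 TPM in A3. Over all genes, the limma F test called 1073 of 5286 genes (20.3%) different between any of the isolates. That count was 633 and 618 without A3 replicate 1 or 2, and 698 without A4 replicate 2.

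Against the mean of the others, isolate A1 had higher expression of most listed type VI secretion genes, of 3 of 42 adhesin and exopolysaccharide genes and of 3 of 19 terminal oxidase genes. Of the 13 genes of the listed type VI secretion cluster PP_3088 to PP_3100, a contractile toxin delivery system, 12 rose. The cluster summed to 2123 ± 208 TPM in A1 against 521 ± 91.8 in A2, 179 ± 3.76 in A3 and 1286 ± 81.7 in A4. Tags outside this range were not searched for type VI genes. The surface adhesin gene PP_0806 stood at 838 ± 44.1 TPM against 87.9 ± 11.9, 9.83 ± 0.720 and 648 ± 94.8 TPM, a log2 change of 3.30 ± 0.11 (SE). The cbb3-type cytochrome oxidase genes PP_4250, PP_4251 and PP_4253 rose by 1.66, 1.69 and 1.40, and each was higher than in every single other isolate. In all, 143 genes were higher and 86 lower in A1 by limma. Against each single other isolate 20 were higher and 2 lower. Of the type VI, adhesin and aromatic breakdown genes 0 were above each single other isolate by limma, and also 0 unadjusted and 0 with voom, adjusted or not. The median change of the type VI list was 1.82, with 0 members lower, 1 not called and 13 higher adjusted over the list alone (camera adjusted p = 8.8e-16; adjusted p = 0.162 with an estimated correlation). Of 19 genes of benzoate, catechol and protocatechuate breakdown, 8 were higher, 0 lower and 11 not called, with 9 higher adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.128 with an estimated correlation). PP_3161 rose by 1.98 ± 0.18 and PP_3715 by 1.57 ± 0.24. In the adhesin and exopolysaccharide list, 3 of 42 were higher (PP_0806, PP_0805 at 2.28 and PP_0168 at 1.02), 0 lower and 39 not called, with 3 higher adjusted over the list alone (camera adjusted p = 1.1e-10; adjusted p = 0.101 with an estimated correlation). In the list of terminal oxidases the 3 named above were higher, 0 of 19 lower and 16 not called, with 3 higher adjusted over the list alone (camera adjusted p = 8.5e-04; adjusted p = 0.314 with an estimated correlation). The isocitrate lyase gene PP_4116 of the glyoxylate list rose by 1.23 ± 0.09. The largest rises outside the lists were PP_3781, at 2126 ± 125 TPM against 12.6 ± 0.944, 4.90 ± 1.12 and 1377 ± 272 (log2 change 5.48 ± 0.14), and PP_3783 at 4.85 ± 0.13. Both lie in a stretch of 16 neighbouring tested genes, PP_3775 to PP_3790, that were all higher. The largest falls were PP_0831, at 25.7 ± 3.12 TPM against 163 ± 1.85, 543 ± 10.1 and 97.6 ± 2.82 (−2.95 ± 0.09), and PP_3963 at −2.86 ± 0.13. With a pseudocount of 10 the number of genes called in A1 was 152.

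Isolate A2 had the fewest called genes on xylose, and most of them were lower. PP_3380, the regulator gene beside the 2-ketogluconate genes, was at 1762 ± 205 TPM in A2 against 3675 ± 31.7 in A1, 3594 ± 16.3 in A3 and 3443 ± 51.2 in A4 (log2 change −1.02 ± 0.08, adjusted p = 0.00022, limma). It was the 1 called gene among the glucose uptake, periplasmic oxidation, 2-ketogluconate, Entner-Doudoroff, sugar acid and introduced genes in any xylose isolate. PP_3380 changed by −0.90 without A2 replicate 1 and by −0.99 with limma voom on recovered reads, both short of 2-fold. Of 18 pyoverdine genes, which make and take up an iron siderophore, 10 were lower, 0 higher and 8 not called, with 13 lower adjusted over the list alone (median −1.21, camera adjusted p = 7.2e-20; adjusted p = 0.196 with an estimated correlation). Of the 19 aromatic breakdown genes 7 were lower, 0 higher and 12 not called, with 10 lower adjusted over the list alone (median −1.09, camera adjusted p = 6.7e-09; adjusted p = 0.101 with an estimated correlation). The superoxide dismutase gene PP_0946 was at 6.19 ± 0.448 TPM and fell by 1.90 ± 0.21 on the log2 scale. The mean in this contrast held A4, where PP_0946 was above every single other isolate, which enlarges the fall. In all 6 genes were higher and 86 lower by limma. Against each single other isolate limma called 0 genes in A2. That count was 1 gene at an unadjusted p under 0.05, and with voom 0 adjusted and 1 unadjusted. Among called genes beyond all other libraries, the largest rises were PP_2737 at 1.16 ± 0.13 and PP_2734 at 1.12 ± 0.10, and the largest falls were PP_5628 at −3.04 ± 0.27, from 35.9 ± 15.1 TPM in A1 and 38.4 ± 4.93 in A4 to 1.01 ± 0.498 in A2, and PP_0943 at −2.56 ± 0.50. PP_5628 was at 2.09 ± 0.0938 TPM in A3, and A2 was not called lower than A3 alone. A stretch of 9 tested genes, PP_3781 to PP_3789, was lower in A2 with a median of −3.33, and did not lie beyond the libraries of A3. PP_0943 lost its call without A2 replicate 1 (adjusted p = 0.0616) or replicate 2 (adjusted p = 0.0861, limma), without A3 replicate 1 or 2, and without A4 replicate 2. It also lost it without a variance trend (adjusted p = 0.0756) and with voom (adjusted p = 0.158). With a pseudocount of 10 the number of genes called in A2 was 57.

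Isolate A3 had the type VI secretion cluster and the adhesin gene PP_0806 at their lowest levels on xylose. All 13 tested type VI genes fell, 8 of them below every single other isolate (5 with voom), with a median change of −2.57. PP_3089 of this cluster was at 112 ± 12.4 TPM in A3 against 1446 ± 77.3 in A1, 335 ± 61.3 in A2 and 810 ± 76.9 in A4. PP_0806, at 9.83 ± 0.720 TPM, fell by 5.07 ± 0.11. PP_0831, at 543 ± 10.1 TPM, and PP_3963, at 6999 ± 808 TPM, rose by 2.85 ± 0.09 and 2.49 ± 0.13 and were the largest rises. In all 20 genes were higher and 272 lower by limma, and 3 higher and 89 lower than in each single other isolate. The type VI list had 0 members higher, 0 not called and 13 lower adjusted over the list alone (camera adjusted p = 4.7e-15; adjusted p = 0.164 with an estimated correlation). Of 42 adhesin and exopolysaccharide genes, 7 were lower, 0 higher and 35 not called, with 7 lower adjusted over the list alone (camera adjusted p = 1.0e-06; adjusted p = 0.101 with an estimated correlation). Of 18 pyoverdine genes, 13 were lower, 0 higher and 5 not called, with 14 lower adjusted over the list alone (camera adjusted p = 1.5e-10; adjusted p = 0.332 with an estimated correlation). The list held 0.0193% ± 0.000616 of all TPM in A3, 0.0207% ± 0.000943 in A2, 0.0358% ± 0.0101 in A1 and 0.156% ± 0.0152 in A4. Of 19 aromatic breakdown genes, 8 were lower, 0 higher and 11 not called, with 8 lower adjusted over the list alone (camera adjusted p = 5.4e-04; adjusted p = 0.162 with an estimated correlation). Among 19 terminal oxidase genes, PP_4250 and PP_4251 were lower, at −1.29 and −1.32, as was PP_0106, with 0 higher, 16 not called and 3 lower adjusted over the list alone (camera adjusted p = 0.0456; adjusted p = 0.580 with an estimated correlation). Of the pyoverdine, aromatic breakdown and terminal oxidase genes 0 were below each single other isolate by limma, and also 0 unadjusted and 0 with voom, adjusted or not. The sugar acid list had 0 of 15 genes called, all 15 not called over the list alone as well, and a median of 0.20 (camera adjusted p = 0.025; adjusted p = 0.804 with an estimated correlation). The largest falls were PP_3781 at −5.86 ± 0.14 and PP_1661, at 16.3 ± 1.60 TPM against 1532 ± 9.76, 301 ± 39.8 and 1090 ± 95.2, at −5.53 ± 0.10. A stretch of 17 tested genes, PP_3774 to PP_3790, was lower throughout. With a pseudocount of 10 the number of genes called in A3 was 184.

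Isolate A4 was marked by higher expression of genes of a prophage region, of a second prophage region and of pyoverdine. The 52 listed genes from PP_1532 to PP_1584, an integrated phage genome, summed to 18565 ± 2923 TPM in A4 against 2325 ± 152 in A1, 2758 ± 187 in A2 and 2378 ± 2.20 in A3. Of the 48 tested, 45 rose with a median change of 3.07, 39 of them above every single other isolate. PP_1574 went from 42.2 ± 0.246, 51.8 ± 6.57 and 43.0 ± 2.36 TPM in A1, A2 and A3 to 865 ± 100 TPM in A4. In the prophage region PP_3849 to PP_3920, 35 of 58 genes rose, among them PP_3877 with a change of 4.36 ± 0.28, and the 64 listed genes summed to 3987 ± 605 TPM in A4 against 2838 ± 264 in A1, 2764 ± 753 in A2 and 2368 ± 176 in A3. Of 18 pyoverdine genes 16 rose, and PP_4217, the pyoverdine receptor gene, was at 708 ± 45.9 TPM against 58.5 ± 25.1, 7.83 ± 0.260 and 7.96 ± 2.24 (5.43 ± 0.23). By limma 234 genes were higher and 2 lower in A4. Against each single other isolate 137 genes were higher and 0 lower, where limma gave 1 lower at an unadjusted p under 0.05 and voom 0 both adjusted and unadjusted. In the first prophage list 0 were lower, 3 not called and 46 higher adjusted over the list alone (camera adjusted p = 1.8e-56; adjusted p = 0.101 with an estimated correlation). In the list PP_3849 to PP_3920, 0 were lower, 23 not called and 39 higher adjusted over the list alone (median 1.57, camera adjusted p = 3.0e-26; adjusted p = 0.128 with an estimated correlation). In the pyoverdine list 0 were lower, 2 not called and 16 higher adjusted over the list alone (median 2.37, camera adjusted p = 9.9e-23; adjusted p = 0.188 with an estimated correlation).

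In A4, 3 of 7 oxidative stress genes and 3 of 7 efflux genes also rose. The oxidative stress list had 3 of 7 higher, 0 lower and 4 not called, with 3 higher adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.208 with an estimated correlation). These were PP_0946, the superoxide dismutase gene, at 3.06 ± 0.21, and the alkyl hydroperoxide reductase genes PP_2439, at 618 ± 66.2 TPM against 162 ± 3.92 to 196 ± 37.7 in the others (1.83 ± 0.11), and PP_2440 at 1.41 ± 0.14. The efflux pump genes PP_3425, PP_3426 and PP_3427 rose by 1.59, 1.43 and 1.49, with 0 of 7 lower, 4 not called and 3 higher adjusted over the list alone (camera adjusted p = 1.9e-04; adjusted p = 0.162 with an estimated correlation). Of the 19 aromatic breakdown genes, 9 were higher, 0 lower and 10 not called, with 10 higher adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.128 with an estimated correlation). Of the 13 type VI genes, 9 were higher, 0 lower and 4 not called, with 10 higher adjusted over the list alone (camera adjusted p = 1.9e-10; adjusted p = 0.196 with an estimated correlation). Of the aromatic breakdown and type VI genes 0 were above each single other isolate by limma, and also 0 unadjusted and 0 with voom, adjusted or not. The type VI genes summed to 1286 ± 81.7 TPM in A4, below the 2123 ± 208 TPM in A1. PP_3522, at 514 ± 27.5 TPM against 14.6 ± 3.04 in A3, the highest of the others, rose by 5.28 ± 0.21 and PP_3796 by 4.43 ± 0.34. The 2 lower genes were PP_4262, at 0.362 ± 0.512 TPM, and PP_0023, at 24.0 ± 1.48 TPM, with changes of −1.49 ± 0.36 and −1.33 ± 0.34. PP_4262 lost its call in 7 of the fits that left out a library, and PP_0023 in 4 of them, up to an adjusted p of 0.329 without A4 replicate 2 for PP_4262 and 0.233 without A4 replicate 1 for PP_0023 (limma). With limma voom on recovered reads both lost it (adjusted p = 0.143 and 0.128), and PP_0023 also without a variance trend (adjusted p = 0.121). The mean that each other isolate was set against held A4, and the prophage list PP_1532 to PP_1584 also had 34 genes lower in A1, 14 in A2 and 24 in A3, and the pyoverdine list 10 in A2 and 13 in A3.

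**Figure D1:**
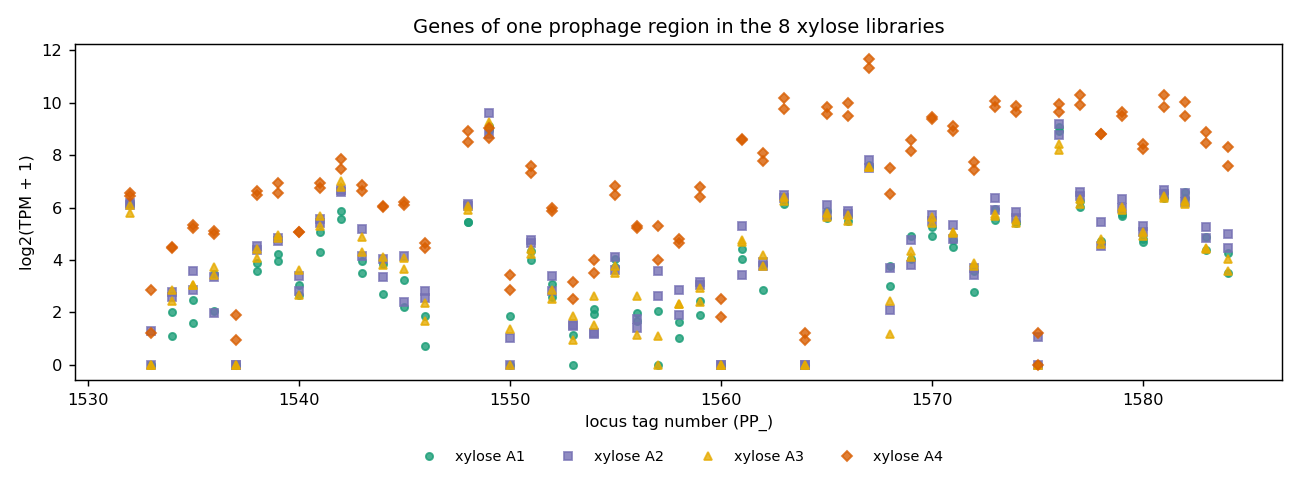
Level of each listed gene of the prophage region PP_1532 to PP_1584 in the 8 xylose libraries, as log2(TPM + 1) on the vertical axis against the locus tag number, with 1 point per library and a colour and symbol per isolate. The A4 points lie above the other isolates for most genes, and 39 of the 48 tested genes were higher in A4 than in every single other isolate.

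On galactose, the isolates differed more. The limma F test called 2805 of 5287 genes (53.1%) different between any of the 3 isolates. The introduced genes galT and galK were highest in isolate 2: galT was at 1204 ± 69.8 TPM there against 598 ± 21.4 in isolate 1 and 636 ± 25.9 in isolate 3, and galK at 1423 ± 44.9 against 760 ± 55.1 and 763 ± 2.71. The introduced gene galM was at 2315 ± 210, 2455 ± 29.8 and 1746 ± 25.1 TPM. PP_1015 of glucose uptake was at 22580 ± 704, 17310 ± 735 and 12921 ± 317 TPM in isolates 1, 2 and 3, and PP_1010 of the Entner-Doudoroff pathway at 840 ± 54.6, 1313 ± 36.6 and 1357 ± 116 TPM. The glucose uptake genes summed to 51067 ± 2501, 51303 ± 1670 and 34938 ± 680 TPM. Scaling mattered more here than on xylose: centring each library on its median ratio moved the median gene by −0.23 in isolate 1 and 0.14 in isolate 2, and quantile normalization by −0.22 in isolate 1 and 0.18 in isolate 3. List medians are therefore also given after centring. With 3 isolates, an isolate that stands apart also enters the means of both others, so the counts against each single other isolate are given beside each contrast.

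Galactose isolate 1 differed in genes of several terminal oxidases, which moved in both directions, in PP_1020 and in exopolysaccharide genes. The aa3-type oxidase genes PP_0103 to PP_0106 rose by 1.63 to 2.52, with PP_0104 at 103 ± 5.43 TPM against 28.3 ± 0.561 and 17.2 ± 2.41. The cyanide-insensitive oxidase genes PP_4650 and PP_4651 rose by 1.59 and 1.55. Of the neighbouring cbb3-type genes, PP_4255, PP_4257 and PP_4258 rose by 1.13, 1.47 and 1.06, while PP_4256 was at 0.97, short of 2-fold. PP_4255 and PP_4258 were short of 2-fold after median centring (0.90 and 0.83) and without isolate 1 replicate 1 (0.99 both). PP_4257 was at 0.57 with a pseudocount of 10 and at 0.88 without isolate 1 replicate 2 (adjusted p = 0.140, limma). The cbb3-type genes PP_4250 to PP_4253 fell, with PP_4250 at 371 ± 30.3 TPM against 853 ± 396 and 2691 ± 966 (−1.96 ± 0.27), as did the bo3-type genes PP_0812 to PP_0815, with PP_0812 at 443 ± 28.4 TPM against 924 ± 111 and 1289 ± 197 (−1.30 ± 0.11). PP_1020, next to the glucose transporter genes, was at 337 ± 7.00 TPM against 2037 ± 67.6 and 1450 ± 54.0, a change of −2.35 ± 0.07 that also held against each single other isolate. By limma 496 genes were higher and 269 lower (64.8% higher). Median centring turned this split to 300 higher and 371 lower (44.7% higher) and quantile normalization to 311 and 348 (47.2% higher). Against each single other isolate 265 were higher and 44 lower. The terminal oxidase list had 9 higher, 8 lower and 2 not called of 19, with 9 and 8 adjusted over the list alone, a median of 0.97 (0.74 after centring) and a camera direction that was downward (adjusted p = 0.569; adjusted p = 0.758 with an estimated correlation). In the adhesin and exopolysaccharide list, 12 were higher, 13 lower and 17 not called of 42, with 12 and 13 adjusted over the list alone (camera adjusted p = 0.315; adjusted p = 0.618 with an estimated correlation). Of these, PP_3132 to PP_3142 were all higher, from 1.39 to 1.99, and the alginate genes PP_1277 to PP_1288, which were high in isolate 2, all lower.

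The lists of ribosomal protein, Entner-Doudoroff and NADH dehydrogenase genes had medians below 0 in galactose isolate 1. The cluster of ribosomal protein genes summed to 32339 ± 389 TPM against 52951 ± 2236 and 53978 ± 5437, with a median change of −0.72 (−0.95 after centring), 1 of 28 lower, 0 higher, 27 not called and 1 lower adjusted over the list alone (camera adjusted p = 2.6e-14; adjusted p = 0.458 with an estimated correlation). The Entner-Doudoroff list had a median of −0.56 (−0.79 after centring) and 0 of 9 genes called, also 0 adjusted over the list alone (camera adjusted p = 3.3e-05; adjusted p = 0.458 with an estimated correlation). The NADH dehydrogenase list had a median of −0.40 (−0.62 after centring) and 0 of 13 called, also 0 adjusted over the list alone (camera adjusted p = 3.1e-05; adjusted p = 0.458 with an estimated correlation). All 13 type VI genes were lower, 1 of them below each single other isolate by limma (with voom 0 adjusted and 1 unadjusted), with 0 higher, 0 not called and 13 lower adjusted over the list alone (camera adjusted p = 9.9e-13; adjusted p = 0.185 with an estimated correlation). PP_3600 of the sugar acid list and PP_3623 of the periplasmic list were higher, at 1.23 ± 0.16 and 1.02 ± 0.11. PP_3623 fell short of 2-fold after median centring (0.79), and both did after quantile normalization (0.96 for PP_3600 and 0.71 for PP_3623). PP_3623 was at 0.99 without isolate 1 replicate 2 and 0.97 without isolate 3 replicate 2. PP_1444 was higher against the mean of the others (2.27 ± 0.10), though not against isolate 3 alone. The largest rises outside the lists were PP_2260, which was at 7.39 ± 1.22 and 3.31 ± 1.35 TPM in isolates 2 and 3 (4.10 ± 0.22), and PP_2262 (3.59 ± 0.17). Among called genes outside the lists and beyond all other libraries, the largest falls were PP_5421 (−4.11 ± 0.18), which was high in isolate 2, and PP_5338, at 21.3 ± 1.38 TPM against 297 ± 7.67 and 126 ± 10.4 (−3.12 ± 0.10). The stretch PP_4461 to PP_4465, also high in isolate 2, was lower with a median of −3.13. With a pseudocount of 10 the number of genes called in isolate 1 was 443.

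Galactose isolate 2 had much lower transcript levels of the periplasmic glucose dehydrogenase gene PP_1444 and higher levels of the type VI secretion and alginate clusters. PP_1444 was at 72.0 ± 9.84 TPM in isolate 2 against 1769 ± 134 in isolate 1 and 1838 ± 157 in isolate 3, a change of −4.63 ± 0.10 (adjusted p = 1.9e-08, limma). Its neighbour PP_1445 was at 14.1 ± 2.94 TPM against 1151 ± 72.6 and 698 ± 46.1, a change of −5.90 ± 0.12. The type VI genes summed to 3337 ± 137 TPM against 210 ± 7.04 and 193 ± 0.0570. All 13 rose above each single other isolate, with a median of 4.53 (4.67 after centring). The alginate genes PP_1277 to PP_1288 all rose, PP_1288 from 0.725 ± 0.0211 and 1.07 ± 0.232 TPM to 236 ± 13.8 TPM (6.97 ± 0.20). By limma 382 genes were higher and 348 lower (52.3% higher), and 321 were higher and 148 lower than in each single other isolate. Median centring gave 436 higher and 248 lower (63.7% higher). The type VI list had 0 lower, 0 not called and 13 higher adjusted over the list alone (camera adjusted p = 1.7e-15; adjusted p = 0.185 with an estimated correlation). In the adhesin and exopolysaccharide list, 13 were higher, 11 lower and 18 not called, with 13 and 11 adjusted over the list alone (camera adjusted p = 0.341; adjusted p = 0.618 with an estimated correlation). The adhesin gene PP_0168 was among those lower, at 55.9 ± 5.37 TPM against 349 ± 19.6 and 358 ± 64.5.

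The flagellar cluster moved in both directions in galactose isolate 2. Of its 67 tested genes 13 were higher, 14 lower and 40 not called, with 13 and 14 adjusted over the list alone (camera adjusted p = 0.472; adjusted p = 0.757 with an estimated correlation). PP_4378, the flagellin gene, fell by 3.56 ± 0.10 on the log2 scale, from 8387 ± 728 and 10010 ± 544 TPM in isolates 1 and 3 to 777 ± 67.6 TPM, and PP_4377 by 3.36 ± 0.19. PP_4384 to PP_4391 rose by 1.33 to 2.59. The introduced genes galT and galK had changes of 0.96 ± 0.08 and 0.90 ± 0.08 (adjusted p = 1.9e-05 and 3.0e-05, limma) and galM of 0.29 ± 0.09, all short of 2-fold. Median centring shifts the genes of this contrast by 0.14, which takes galT and galK past 2-fold but not galM. PP_1020 was 1.54 ± 0.07 higher. In the glucose uptake list PP_1020 was the 1 higher, with 0 lower, 5 not called and 1 higher adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.618 with an estimated correlation). The largest rises outside the lists were PP_5421, from 6.80 ± 2.28 and 10.8 ± 1.83 TPM to 1482 ± 154 TPM (7.29 ± 0.18), and PP_0014, from 17.5 ± 1.40 and 17.1 ± 0.483 TPM to 2374 ± 134 TPM (7.02 ± 0.09). The largest falls outside the lists were PP_1445 and PP_0831, the second of them at 11.7 ± 2.67 TPM against 508 ± 20.6 and 259 ± 24.1 (−4.85 ± 0.13).

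Galactose isolate 3 had the highest transcript levels of the cbb3-type oxidase genes PP_4250 to PP_4253 and the lowest sum of glucose uptake transcripts on galactose. PP_4250, PP_4251, PP_4252 and PP_4253 rose by 2.25, 2.33, 2.44 and 2.34, each above every single other isolate. PP_4253 was at 3412 ± 1406 TPM against 480 ± 27.1 in isolate 1 and 888 ± 262 in isolate 2. The catalase gene PP_0481 was at 124 ± 38.3 TPM against 34.5 ± 2.88 and 51.9 ± 15.1, a change of 1.51 ± 0.21. PP_1015 and PP_1016 of glucose uptake were −0.61 ± 0.12 and −0.66 ± 0.09 (adjusted p = 0.0059 and 9.6e-04, limma), short of 2-fold. The glucose uptake list, whose sum in isolate 3 was 34938 ± 680 TPM, had 0 of 6 genes called, also 0 adjusted over the list alone, and a median of −0.57 (−0.48 after centring, camera adjusted p = 0.129; adjusted p = 0.706 with an estimated correlation). Its member PP_1020 was lowest in isolate 1. By limma 98 genes were higher and 313 lower, and 31 were higher and 31 lower than in each single other isolate. The terminal oxidase list had 5 higher, 6 lower and 8 not called, with 5 and 6 adjusted over the list alone, a median of −0.48 (−0.39 after centring) and an upward camera direction (adjusted p = 0.489; adjusted p = 0.753 with an estimated correlation). PP_0812 was the fifth higher member, and PP_0103 to PP_0106, PP_4650 and PP_4651 were the lower ones, from −1.60 to −1.02. Against each single other isolate 4 members of this list were higher and 0 lower by limma and with voom, adjusted or not. The ATP synthase genes had 0 of 8 called, also 0 adjusted over the list alone, and a median of 0.42 (0.51 after centring, camera adjusted p = 2.7e-05; adjusted p = 0.382 with an estimated correlation). PP_1444 was 2.36 ± 0.10 above the mean of the others, which holds the low value of isolate 2, and it was not called higher than in isolate 1 alone. Outside the lists, PP_0173 rose from 126 ± 8.43 and 17.6 ± 0.537 TPM to 321 ± 28.1 TPM (2.73 ± 0.10) and PP_0563 by 2.23 ± 0.11. PP_0035 was listed at 0 TPM in both libraries of isolate 3, against 2.08 ± 0.982 in isolate 1 and 46.9 ± 15.7 in isolate 2, and PP_4461 fell by 3.55 ± 0.14. All 13 type VI genes were lower than the mean that held isolate 2, with 0 higher, 0 not called and 13 lower adjusted over the list alone (camera adjusted p = 8.7e-10; adjusted p = 0.185 with an estimated correlation). With a pseudocount of 10 the number of genes called in isolate 3 was 263.

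**Figure D2:**
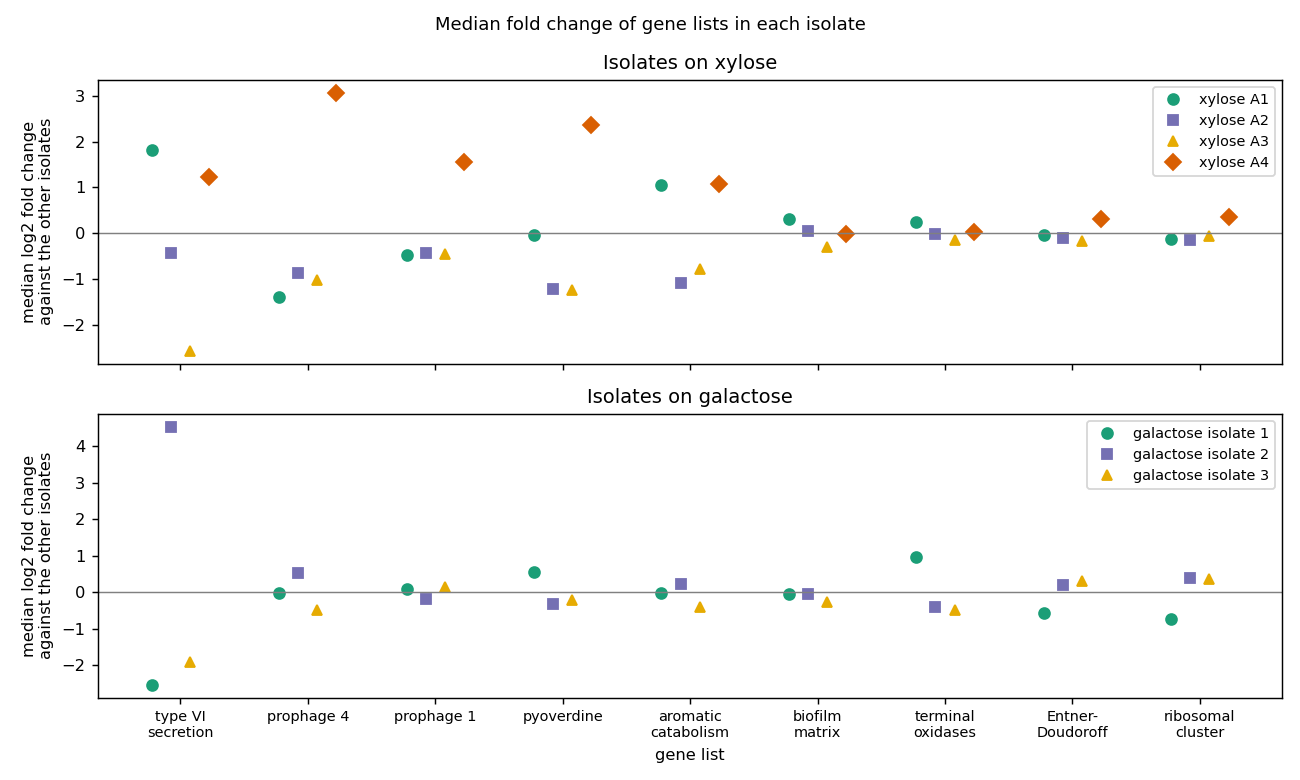
Median log2 fold change, on the log2(TPM + 1) scale, of the tested members of 9 gene lists in each isolate against the other isolates on its sugar, with 1 point per isolate. Prophage 4 is the region PP_1532 to PP_1584 and prophage 1 the region PP_3849 to PP_3920. On xylose A4 stands highest for both prophage lists (3.07 and 1.57) and pyoverdine (2.37), and on galactose isolate 2 for type VI secretion (4.53). A median can cover members that moved both ways, as for the terminal oxidases in galactose isolate 1. Medians close to 0 can change sign with the scaling, as that of biofilm matrix in galactose isolate 2 did (−0.04, and 0.10 after median centring).

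Set side by side, the largest differences towards xylose among genes whose isolate means did not overlap were in genes of sugar breakdown. Towards galactose the 10 largest held Entner-Doudoroff genes and also genes outside the lists. Strain, sugar and table were the same split and the tables were made separately, so no test was run across them and the values describe these isolates. Glucose uptake and Entner-Doudoroff genes were higher on galactose. PP_1010 was at 57.2 to 74.8 TPM on xylose and 840 to 1357 TPM on galactose, and PP_1015 at 2387 to 2667 TPM on xylose and 12921 to 22580 TPM on galactose. Sugar acid and 2-ketogluconate genes were higher on xylose, where PP_2834 was at 7452 to 9373 TPM against 18.9 to 27.8 TPM on galactose and PP_3377 at 6867 to 9693 TPM against at most 46.6 TPM. PP_1444 was at 145 to 218 TPM on xylose, between the level of galactose isolate 2 and those of isolates 1 and 3. Of 5299 genes, the isolate means of 1554 (29.3%) did not overlap between the sugars, where chance gives 5.71%. Of these 105 were at least 4-fold higher on xylose and 47 on galactose. All 6 glucose uptake genes and 8 of 9 Entner-Doudoroff genes were among those higher on galactose, with medians of −3.02 and −4.17 (log2, xylose minus galactose). On xylose 5 of 8 2-ketogluconate and gluconate genes, 5 of 15 sugar acid genes and 3 of 7 periplasmic oxidation genes were higher, the last being the gluconate dehydrogenase genes PP_3382, PP_3383 and PP_3384 at 2.94, 3.28 and 4.66. Among the genes without overlap, the largest differences were PP_2585 (8.71), PP_2834 (8.47), PP_2835 (8.27), PP_2836 (8.08) and PP_3379 (8.03) towards xylose, with PP_1659 (5.43) the largest outside the lists. PP_1659 varied widely among the xylose isolates, with log2 means of 4.05 to 10.4 against 2.54 to 2.86 on galactose. It fell by 5.42 in A3 against the other xylose isolates. Towards galactose they were PP_1009 (−5.28), PP_1024 (−4.97), PP_1022 (−4.90) and PP_1023 (−4.78), with PP_2645 (−4.86) and PP_2646 (−4.52) the largest outside the lists.

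**Figure D3:**
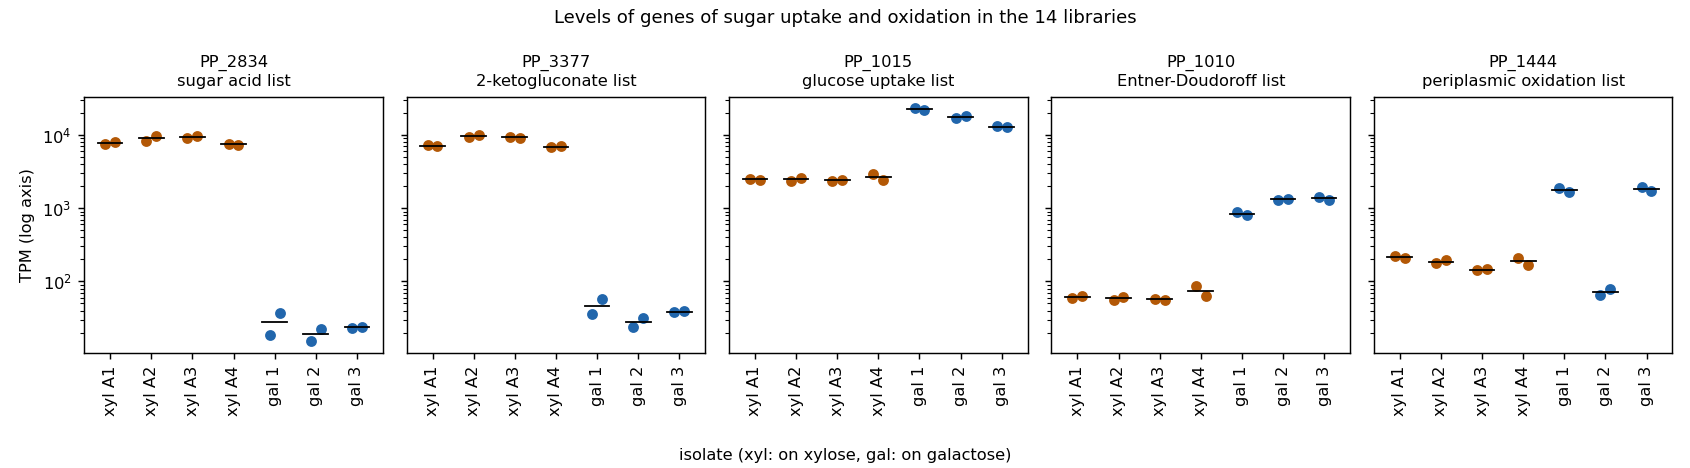
Level in TPM, on a log axis, of a gene from each of 5 lists in the 4 xylose isolates (brown) and the 3 galactose isolates (blue), with points for the 2 libraries of each isolate and a line at their mean. PP_2834 and PP_3377 have means of at least 6867 TPM on xylose and at most 46.6 TPM on galactose, PP_1015 and PP_1010 are higher on galactose, and PP_1444 is lowest in galactose isolate 2 at 72.0 TPM.

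Many of the called genes were neighbours, as genes of shared operons and regions are. Runs of at least 5 neighbouring tested genes called in the same direction held 67 of the 229 genes in A1, 30 of 92 in A2, 89 of 292 in A3 and 122 of 236 in A4. On galactose they held 137 of 765 in isolate 1, 174 of 730 in isolate 2 and 112 of 411 in isolate 3. Shuffling the gene order 1000 times gave at most 10 genes in such runs in any of the contrasts. In A4 the longest runs were PP_1550 to PP_1584 (32 genes, median 3.81) and PP_4209 to PP_4223 (15 genes, median 2.56). In galactose isolate 2 they were PP_2610 to PP_2627 (18 genes, median 3.54), PP_1940 to PP_1952 (13 genes, median 2.33) and the type VI cluster PP_3088 to PP_3100 (13 genes). With runs of at least 3 genes, the sum over all contrasts was 1102, where a gene counts once for each contrast that has it in a run.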

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

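The fit with voom was chosen after the data were seen, the added list after the tags but before the values were seen, and the other alternatives before the data were examined. Of 215 values of 12 counts under the alternatives, 189 stayed within 1.5 times the count reported and 26 did not. With a pseudocount of 10, which shrinks changes of low genes, 152 genes were called in A1, 57 in A2, 184 in A3, 443 in galactose isolate 1 and 263 in isolate 3. Runs then held 414 genes summed over contrasts, where a gene can count more than once. With no fold limit the calls were 796, 222, 878 and 479 in A1 to A4, and 2605, 2128 and 1287 in galactose isolates 1 to 3. Against every other isolate they were 22, 0, 92 and 137, and 309, 469 and 62. In A2 limma called 1 gene at an unadjusted p under 0.05 in this comparison, and voom 0 adjusted and 1 unadjusted. Leaving out 1 library moved the xylose F test between 618 and 1399 genes, with 633 and 618 without A3 replicate 1 or 2 and 698 without A4 replicate 2, and the cause was not tested. Voom gave 1433 and 2974 genes in the F tests. A 2-fold limit gave 551 genes between the sugars, and runs of 3 held 1102 genes summed over contrasts. The gene lists had 0 calls with an estimated correlation against 69 reported, and with fry 61 of the 69 were called. Under the remaining list settings 1112 of 1171 values kept their call and 0 reversed. Of 133 results for named genes, 116 kept their call under every alternative run, and of 2256 values 69 lost it and 0 reversed.

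With the replicate block, the F tests called 957 genes on xylose and 2651 on galactose, the contrasts 225, 91, 291 and 236 in A1 to A4 and 764, 724 and 414 in galactose isolates 1 to 3, with 67 list calls and 743 genes in runs summed over contrasts. PP_4262 and PP_0023 in A4 were not called (adjusted p = 0.0547 and 0.0574, limma). Libraries with the same number shared little, with correlations of their deviations from −0.276 to 0.169 on xylose and −0.049 to 0.075 on galactose. The numbers were therefore not taken as pairs.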

Other observations

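The tests of region copies and scaling for the prophage, the shifts along the gene order and all tests for PP_1444 and PP_1445 were chosen after the result was seen, and the others before. Smaller shifts were found in lists not described above. In galactose isolate 3, 3 of 31 genes of the prophage region PP_3026 to PP_3066 were higher, 0 lower and 28 not called, with 3 higher adjusted over the list alone (median 0.48 and 0.56 after centring, camera adjusted p = 3.3e-05; adjusted p = 0.458 with an estimated correlation). In galactose isolate 1, 2 of 13 chaperone and protease genes were lower, 0 higher and 11 not called, with 2 lower adjusted over the list alone (median −0.76 and −0.99 after centring, camera adjusted p = 2.7e-05; adjusted p = 0.458 with an estimated correlation). The polyhydroxyalkanoate genes of that isolate had 1 of 6 higher, 0 lower and 5 not called, with 1 higher adjusted over the list alone (median 0.73 and 0.51 after centring, camera adjusted p = 0.0163; adjusted p = 0.458 with an estimated correlation). Runs outside the lists in galactose isolate 2 included PP_4071 to PP_4085, with 12 higher genes and a median of 3.61, and PP_4461 to PP_4465, with 5 higher genes and a median of 6.41. What the tags of these runs encode was not checked, so a shared function with a list is not excluded.

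The prophage genes PP_1532 to PP_1584 were higher in A4 than in the other xylose isolates. Phage DNA left in the RNA would add a like TPM to every gene, but the 90th percentile of the added TPM (855) was 57.3 times the 10th (14.9). More copies of the whole region would by themselves raise its genes by 1 factor. Over the 39 of 48 tested genes that were not at low levels in the other isolates, the SD of the log2 fold changes was 7.29 times their median standard error. This argues against more copies as the only cause, while copies together with unequal changes in expression stay open. Scaling of the libraries is also argued against, since the median change was 2.98 after quantile normalization. Induced expression of the prophage genes in A4 may be involved, a hypothesis from the same data that none of these tests addressed directly.

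Genes lower in A3 overlapped with those higher in galactose isolate 2: 55 were shared, against 18.6 for independent lists of 271 and 360 among 5243 genes (2.96 times), including all 13 type VI genes and 16 genes of PP_3774 to PP_3790, and it was 1 of 48 pairs of call lists across the sugars. It is not particular to A3 or to isolate 2: A1 enters the mean that A3 was set against, and genes higher in A1 shared 44 against 9.82 with those higher in isolate 2 (4.48 times), 41 against 6.93 with those lower in isolate 1 (5.92 times) and 19 against 2.67 with those higher in isolate 3 (7.11 times), while genes lower in A3 shared 3.12 and 3.02 times as many as independent lists with those lower in isolates 1 and 3 and 2.57 times as many with those higher in isolate 3. Random genes matched on level and replicate spread shared 21.6 on average and at most 40, so that 0 of 10000 draws reached 55 (0.010% is the smallest share such draws can give). These draws treat neighbours as independent and were not matched on variation between isolates. They therefore cannot tell whether the shared genes are ones that vary between isolates in general. Shifting 1 list along the gene order, which keeps stretches of neighbours but not levels, gave 18.6 on average and at most 48 in 5242 shifts (0.0191% with the observed order counted), and after quantile normalization of both tables the overlap was 3.18 times that of independent lists. No biological explanation was tested, nor an effect of level and neighbours together, and a difference in culture density at sampling stays open because no density per library was used here.

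PP_1444 and PP_1445 were much lower in galactose isolate 2. Scaling is argued against, since the weakest fall over both genes and scalings was −4.49. The recovered reads in the 2 libraries of isolate 2 were 855 and 1136 for PP_1444 and 118 and 96 for PP_1445. Loss of PP_1445 or of both genes cannot be told apart from low expression, because the reads may have been carried over from the other isolates' libraries. Carry-over would leave alike shares of both genes, with a ratio near 1. Of the levels in isolates 1 and 3, 3.54 to 4.46% was left for PP_1444 and 1.05 to 2.32% for PP_1445. In replicates 1 and 2 the shares differed by ratios of 2.61 and 4.26 with isolate 1 taken as the source. They differed by 2.06 and 3.36 with the mean of both, and by 1.52 and 2.49 with isolate 3. The limit set for arguing against carry-over was a ratio of at least 2 in each replicate. With isolate 3 as the source, replicate 1 fell short of it. The ratios therefore cannot tell whether carry-over from isolates 1 and 3 was the only source of the reads. Carry-over as a part of the reads of either gene stays open. No biological explanation was tested.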
